A study of Homo sapiens with 12 samples.

How the data were processed

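Total RNA of the bone marrow derived leukemia line MV-4-11 was sequenced in 12 libraries, 3 for each of DMSO, eliglustat (ELI), venetoclax (ABT) and both drugs (Comb), per the labels. Cells were treated for 48 h, per the series design text, and doses are not given in the sources used here. Groups and replicate numbers were taken from the sample titles. The authors deposited a single table of FPKM values (reads per kilobase of gene model and scaled to the reads of the library, per the file headers) with 20036 genes by Ensembl identifier and 1 column per library. The aligner, counting tool, genome build and annotation are not given in the sources used here. Of these genes, 3675 were 0 in all libraries and 20011 had a symbol in the name table used.

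The design written before the data were examined took raw counts as the likely unit and named a fallback for normalized values, and since the table holds FPKM values the fallback was the test used. The choices made before the data were examined were the groups, the 7 contrasts, the test, the threshold, the other settings to be tried, 37 gene lists and the rule for naming genes. FPKM values were transformed as log2(FPKM + 1), genes of at least 1 FPKM in 3 or more libraries (9959) were kept, and limma 3.58.1 in R 4.3.3 fitted 1 model of 4 group means to all 12 libraries, with moderated variances that followed the mean and were robust to outlying genes. Benjamini-Hochberg adjustment was made over the 9959 genes within a contrast, at a threshold of 0.05. The contrasts were the 6 pairs of groups and the interaction, (Comb minus ABT) minus (ELI minus DMSO). Genes past the threshold in Comb against DMSO, ABT and ELI in 1 direction made up the combination-enhanced set.

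Low values of a gene were whole multiples of 1 step per library, so reads could be recovered. With a tolerance of 1e-05 from a whole number, and 0.001 in a second pass, all 16361 genes above 0 (100.0%) gave whole reads. Recovered totals were 17259905, 20191505 and 20258249 reads for DMSO replicates 1 to 3, and 17958962, 18420177 and 21082313 for ELI. They were 19311758, 18047269 and 19847590 for ABT, and 19366264, 20121941 and 19654595 for Comb. At this depth 1 read of a 5 kb gene model is worth 0.0095 to 0.0116 FPKM, far under the filter of 1 FPKM. The spread between libraries of a group was larger than counting noise in every pair (chi-square per degree of freedom 2.71 to 83.68), so no library was a copy of another, which does not tell separate cultures from separate preparations of 1 culture. Reads recovered for the genes of the table made up 100.0% of the recovered total in each library. The authors' FPKM scaling thus divides by the reads assigned to these genes, and a shift of a few abundant genes moves all others. Median log2 differences over all genes stayed within 0.03 of 0 under each scaling tried.

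Gene lists held 1184 genes of pathways and cell types that fit the line and the drugs, and 33 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over lists within a contrast. Camera was repeated with an estimated correlation, and fry, which asks whether the genes of a list move 1 way on balance, was run beside it. The 4 lists of other cell types were described and not tested. For each contrast the genes named were UGCG, BCL2 and RAB32, the 8 higher and 8 lower genes with the largest change among called genes with a mean of at least 5 FPKM whose libraries did not overlap (not required for the interaction), and up to 4 members with the smallest adjusted p from each list that passed camera or had 3 or more called members. For the combination-enhanced set the 6 higher and 6 lower genes with the largest summed change against ABT and ELI were named. Some genes that met these rules are not reported here.

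Settings chosen before the data were examined were median-of-ratios scaling, no filter, a filter of 1 CPM on recovered reads, pseudocounts of 0.1 and 0.5, the replicate number as a block, only the 6 libraries compared, and leaving out each library in turn. Settings added after seeing the data were limma's voom on recovered reads, rescaling to reads outside mitochondrially encoded genes, leaving out the 4 libraries numbered 1, the block in fits of 6 or 9 libraries, and removal of a trend on GC content and gene length, alone and with the block. GC content was taken from the longest protein-coding transcript of each gene in GENCODE 29 (9947 of 9959 genes, 99.9%), length was recovered from the FPKM steps, and a loess curve (degree 1, span 0.5) of each library's deviation from the gene means was subtracted. Only 1 form of this correction was tried.

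Whether replicate numbers pair the samples was checked from the correlation, across genes, of the deviations of same-numbered libraries from their group means. It was 0.24 to 0.82 for DMSO with ELI, 0.39 to 0.88 for DMSO with ABT and 0.26 to 0.74 for ELI with ABT, so the numbers were taken to pair these 3 groups, which comes from the data and not from the labels. Only number 1 is clear in all 3 pairs of groups. A differently numbered library came closer for DMSO with ABT at number 2 (0.73 against 0.39), ELI with ABT at number 2 (0.57 against 0.38) and DMSO with ELI at number 3 (0.34 against 0.24). With Comb it was -0.40 to 0.16, which does not pair. The reported fit was set before the data were examined and leaves this pairing out. The block in the fit of 12 libraries applies the numbers to Comb as well.

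The test was tested on simulated data with known changes before use. For ELI against DMSO it recovered 24% of genes changed 1.25-fold, 54% of those changed 1.5-fold, 88% of those changed 2-fold and 100% of those changed 4-fold among 9842 genes, and for ABT against DMSO 8%, 64%, 88% and 100% among 9829 genes. Wrong calls made up 2.7 to 7.8% of calls over the 6 pairs. In a simulated ELI against DMSO comparison of 9835 genes the list test called a list of 40 genes raised 1.3-fold and 0 of 32 random lists, with and without the trend removed. Both simulations drew the noise of each gene independently. They therefore do not give error rates where same-numbered libraries deviate together or genes of a list move together. The simulated trend on GC content was also weaker, with a rho of -0.14 against -0.48 in the real ELI minus DMSO. Gene coordinates are from GRCh38 with GENCODE 29 and were matched by Ensembl identifier. Scripts also used statmod 1.5.0, the data.table package (1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.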

Results

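RNA sequencing measured transcript levels in MV-4-11 cells, an established myelomonocytic acute myeloid leukemia line that carries a KMT2A-AFF1 fusion and an internal tandem duplication of the receptor kinase FLT3. The 12 libraries fell into 4 groups of 3: vehicle (DMSO), eliglustat (ELI), venetoclax, also known as ABT-199 (ABT), and both drugs together (Comb), each after 48 h. Eliglustat inhibits glucosylceramide synthase, the enzyme encoded by UGCG that makes the first glycosphingolipid from ceramide. Venetoclax binds the pro-survival protein BCL2 and releases pro-death proteins held by it. The series title concerns UGCG, venetoclax sensitivity and the small GTPase RAB32 at contacts between the endoplasmic reticulum and mitochondria. Library totals of reads assigned to the genes of the table, read back from the deposited FPKM values, were 17259905 to 21082313. Of the genes in the table, 9959 reached 1 FPKM in at least 3 libraries and were tested with limma. Differences between groups are given on the log2(FPKM + 1) scale, which understates changes of low genes. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

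The groups were ordered by eliglustat along the main axis of variation. The first principal component held 75.5% of the variance and set the DMSO and ABT libraries (-35.4 to 0.6) apart from the ELI and Comb libraries (10.6 to 29). The second held 14.1% and was highest in DMSO replicate 1 (24.3), ELI replicate 1 (11.1) and ABT replicate 1 (5.3). Replicate 1 of these 3 groups stood apart from replicates 2 and 3, and its deviation from the group mean followed the GC content of the genes: Spearman's rho across genes was -0.79 in DMSO replicate 1, -0.70 in ABT replicate 1 and -0.70 in ELI replicate 1, against 0.81 in DMSO replicate 2. In the Comb libraries it lay between -0.29 and 0.26. The group differences followed GC content too, with a rho of -0.48 for ELI minus DMSO, 0.66 for ABT minus DMSO, -0.38 for Comb minus DMSO, -0.54 for Comb minus ABT, -0.06 for Comb minus ELI and -0.62 for ELI minus ABT. Genes are not independent replicates in these correlations. Mitochondrially encoded transcripts took 5.0 to 7.4% of the reads assigned to genes in a library.

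**Figure D1:**
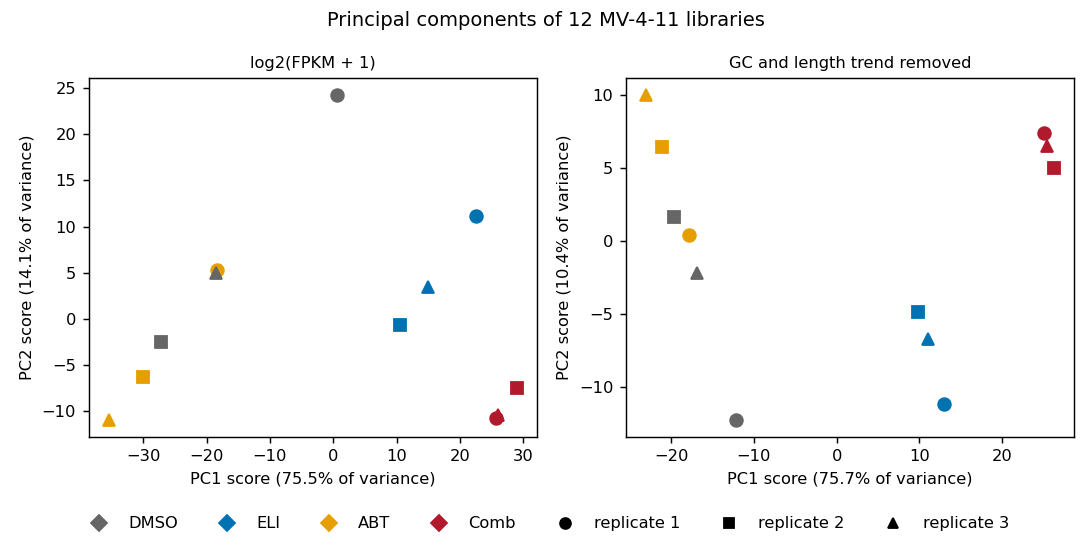
Principal components of the 12 libraries, coloured by group with a symbol for each replicate number, on the log2(FPKM + 1) scale (left) and with the trend on GC content and gene length removed (right). On the left PC1 (75.5% of the variance) sets ELI and Comb apart from DMSO and ABT, and replicate 1 of DMSO, ELI and ABT is highest on PC2 (14.1%) within its group.

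The drug targets and the gene named in the title were followed in every group. UGCG (ENSG00000148154), on the plus strand of chromosome 9 from 111896766 to 111935369 in GRCh38 with GENCODE 29, is a protein-coding gene and was expressed at 171 ± 40.9 FPKM (SD, n = 3) in DMSO, 288 ± 23.8 in ELI, 127 ± 19.7 in ABT and 252 ± 8.02 in Comb. The transcript of the enzyme that eliglustat inhibits thus rose under eliglustat, by 0.77 (SE 0.15, limma adjusted p = 0.0024) against DMSO, and by 0.99 (SE 0.15, limma adjusted p = 0.00016) when eliglustat was added to venetoclax. UGCG differed by -0.41 (SE 0.15) between ABT and DMSO, short of the threshold (limma adjusted p = 0.20, 0.046 without DMSO replicate 2). With the replicate number as a block it did not pass in the fit of 12 libraries (limma adjusted p = 0.076). In block fits added after seeing the data it passed with 6 libraries (limma adjusted p = 0.0089), with the 9 libraries of DMSO, ELI and ABT (0.018) and with the trend on GC content and length removed (0.026). RAB32 (ENSG00000118508), which anchors protein kinase A at mitochondria, lies on the plus strand of chromosome 6 from 146543693 to 146554965. Its level was 20.5 ± 2.77 FPKM in DMSO, 20.4 ± 1.60 in ELI, 22.3 ± 3.36 in ABT and 29.4 ± 1.60 in Comb (SD, n = 3). RAB32 rose in Comb by 0.51 (SE 0.11, limma adjusted p = 0.0030) against DMSO, by 0.39 (limma adjusted p = 0.0086) against ABT and by 0.50 (limma adjusted p = 0.013) against ELI. The last call was lost without Comb replicate 1 (limma adjusted p = 0.062), Comb replicate 3 (0.057) or ELI replicate 1 (0.062). RAB32 differed by 0.00 (SE 0.11) in ELI and 0.11 (SE 0.11) in ABT against DMSO, and neither passed. The departure of Comb from the sum of the single drugs was 0.39 (SE 0.16) for RAB32 and did not pass (limma adjusted p = 0.18, range 0.022 to 0.36), although it did once the trend with GC content and gene length was removed (0.41, limma adjusted p = 0.027). BCL2 (ENSG00000171791), on the minus strand of chromosome 18 from 63123346 to 63320128, was at 22.3 ± 2.99 FPKM in DMSO, 26.2 ± 0.366 in ELI, 20.6 ± 2.44 in ABT and 27.0 ± 0.831 in Comb (SD, n = 3). BCL2 rose by 0.38 (SE 0.10, limma adjusted p = 0.0043) in Comb against ABT and by 0.34 (limma adjusted p = 0.0097) in ELI against ABT. Against DMSO, BCL2 in Comb was 0.27 higher (limma adjusted p = 0.033), a call lost without Comb replicate 1 (0.070), 2 (0.10) or 3 (0.062) and without DMSO replicate 2 (0.12) or 3 (0.10). BCL2 in ELI was 0.23 above DMSO (limma adjusted p = 0.079, 0.035 with the replicate number as a block and 0.0045 without DMSO replicate 1).

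**Figure D2:**
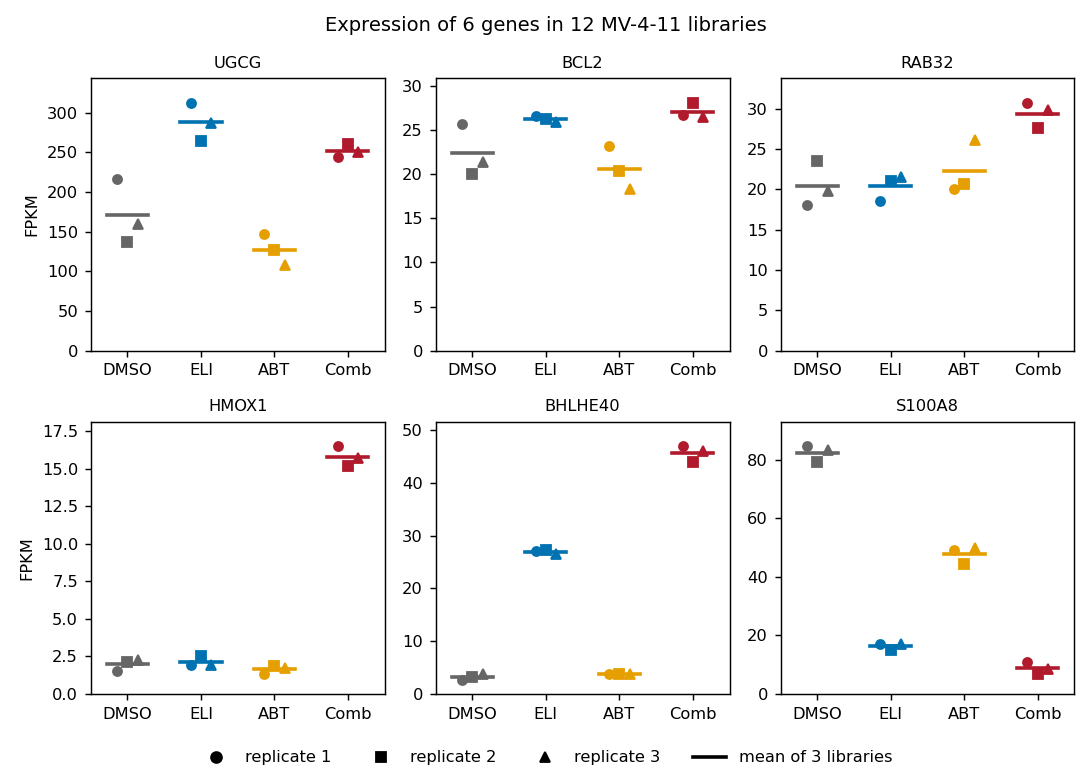
FPKM of UGCG, BCL2, RAB32, HMOX1, BHLHE40 and S100A8 in each of the 12 libraries, with a symbol for each replicate number and a line at the mean of 3 libraries. RAB32 is near 20 FPKM in DMSO and ELI with a mean of 29.4 in Comb, while mean HMOX1 is 15.8 in Comb and 2.14 or lower in the other groups.

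Eliglustat alone lowered transcripts of DNA replication and raised those of NF-kB signalling and endoplasmic reticulum folding. The single genes S100A8 and S100A9, which encode calcium-binding alarmins, fell as well. Many genes of sterol synthesis, fatty acid synthesis and lysosomes rose too, in lists whose calls were lost with an estimated correlation (adjusted p = 0.067, 0.086 and 0.086). Against DMSO, the largest rises were of BHLHE40, a basic helix-loop-helix repressor (2.74, SE 0.08), IL4I1, a secreted amino acid oxidase (2.67, SE 0.11), the collagen chain COL6A1 (2.09), the sialic acid receptor SIGLEC6 (2.02), the galectin LGALS2 (1.94), the lipid scavenger receptor CD36 (1.85), IL7R (1.83) and KLF6 (1.71). BHLHE40 went from 3.19 ± 0.534 to 26.9 ± 0.445 FPKM (SD, n = 3). S100A8 fell by 2.27 (SE 0.13), from 82.3 ± 2.87 to 16.3 ± 1.22 FPKM, and its partner S100A9 fell by 1.94. IGLL1, the surrogate light chain gene, fell by 1.93, PLAC8 by 1.67, the myeloid progenitor marker MS4A3 by 1.26 and the immediate early gene EGR1 by 1.22. All of these had limma adjusted p-values of 0.00026 or lower. Among 47 tested genes of S phase and replication, 40 fell, 0 rose and 7 did not pass (41 fell when adjusted over the list alone). They included the licensing factor CDT1 (-0.91), UHRF1 (-0.83), RFC5 (-0.76) and the ribonucleotide reductase subunit RRM2 (-0.56), and the list was lower than other genes (median -0.57, camera adjusted p = 2.5e-19, adjusted p = 0.00029 with an estimated correlation). NF-kB and inflammatory genes rose in 18 of 19 cases and fell in 1 (the same numbers adjusted over the list alone), with RELB at 1.41, CCL2 at 1.32, NFKB2 at 1.14 and the adhesion molecule ICAM1 at 1.14 (camera adjusted p = 1e-08, adjusted p = 0.046 with an estimated correlation). Cholesterol synthesis genes driven by SREBP2 rose in 15 of 25 cases, fell in 1 and did not pass in 9 (16 and 1 adjusted over the list alone). The sterol sensor partner INSIG1 (1.70), SQLE (0.98) and LSS (0.85) led, and the list had a camera adjusted p of 3.6e-06 (adjusted p = 0.067 with an estimated correlation). Fatty acid synthesis genes rose in 13 of 17 cases and fell in 0 (the same adjusted over the list alone), among them the desaturase SCD (0.83) and FASN (0.68), with a camera adjusted p of 7.9e-06 (adjusted p = 0.086 with an estimated correlation). Lysosome genes rose in 25 of 44 cases and fell in 4 (29 and 4 adjusted over the list alone), including the autophagy receptor SQSTM1 (1.24), cathepsin CTSH (1.03) and the cholesterol carrier NPC2 (0.63), with a camera adjusted p of 3.7e-06 (adjusted p = 0.086 with an estimated correlation). Unfolded protein response genes rose in 16 of 29 cases and fell in 2 (17 and 2 adjusted over the list alone), with the chaperone HSPA5 at 0.57 and HERPUD1 at 0.51 (camera adjusted p = 0.00061, adjusted p = 0.046 with an estimated correlation). Of 39 glycosphingolipid and ceramide genes, the class of the drug's target, 14 rose, 4 fell and 21 did not pass (15 and 4 adjusted over the list alone), with acid ceramidase ASAH1 at 1.36 (camera adjusted p = 0.016, adjusted p = 0.079 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell in 33 of 70 cases and rose in 1 (36 and 1 adjusted over the list alone), with UQCRC1 at -0.72 and NDUFV1 at -0.56, and the call was lost with an estimated correlation (camera adjusted p = 9.8e-06, adjusted p = 0.34 with an estimated correlation). Members of the BCL2 family went both ways, 7 up and 3 down of 18 (7 and 4 adjusted over the list alone, camera adjusted p = 0.24). The pro-death genes BCL2L11 (0.91) and BBC3 (0.65) and the pro-survival gene BCL2A1 (0.83) rose while the pro-death gene BIK fell by 1.00. Genes of contacts between the endoplasmic reticulum and mitochondria also split, 10 up and 10 down of 50 (the same adjusted over the list alone, camera adjusted p = 0.89), with RAB38 at 0.79 and the calcium channel ITPR3 at -0.70. In all, limma called 3600 genes, 1629 higher and 1971 lower, of which 97 changed by at least 1 on the log2 scale. The 3 and 3 libraries did not overlap for 40.5% of genes, where chance gives 10%. The count was 5871 without DMSO replicate 1 and 2291 without ELI replicate 1, and the glycosphingolipid call was lost without the libraries numbered 1 (camera adjusted p = 0.076).

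In the fit of 12 libraries without a block, which leaves the pairing of DMSO and ABT out, venetoclax alone left few genes past the threshold. All of them were lower than in DMSO. The transcription factor gene FOS fell by 0.67 (SE 0.07, limma adjusted p = 0.0027), from 36.1 ± 1.54 to 22.3 ± 1.48 FPKM (SD, n = 3). MPEG1, which encodes a macrophage pore-forming protein, fell by 0.59 (SE 0.06, limma adjusted p = 0.0027), and the hormone gene PRL fell by 0.68 (SE 0.08, limma adjusted p = 0.0039). These 3 calls held without any 1 library and were lost only when DMSO and ABT were fitted alone (limma adjusted p = 0.27 for FOS, 0.38 for MPEG1 and 0.27 for PRL). The histone gene H2AC6 (-0.56), the antigen presentation gene HLA-DRA (-0.51) and the adhesion gene JAML (-0.50) fell, calls that were lost without ABT replicate 2 (limma adjusted p = 0.070, 0.075 and 0.075) or DMSO replicate 3 (0.056, 0.064 and 0.056). S100A8 fell by 0.77 (limma adjusted p = 0.041) and lost the call without ABT replicate 1 (0.067), 2 (0.23) or 3 (0.13) or DMSO replicate 1 (0.086) or 3 (0.15). Among 28 immediate early genes 4 fell, 0 rose and 24 did not pass (12 fell and 1 rose adjusted over the list alone). That list had a camera adjusted p of 0.0050 (adjusted p = 0.18 with an estimated correlation, 0.0092 with the trend on GC content and length also removed). No member of the MYC target and nucleolar list, whose genes build ribosomes, passed over all genes, although adjusted over the list alone 28 of 41 rose and 0 fell. As a list it was higher than other genes (median 0.25, camera adjusted p = 2.9e-11, adjusted p = 0.011 with an estimated correlation). Genes of mitochondrial ribosomes and import had 0 calls among 34 over all genes and 5 higher adjusted over the list alone (median 0.17, camera adjusted p = 6.7e-05, adjusted p = 0.13 with an estimated correlation, 0.044 with the trend also removed). Lists of nuclear oxidative phosphorylation (70 genes, camera adjusted p = 0.00041), glycolysis (21, 0.00064), mitochondrially encoded genes (13, 0.0074) and the integrated stress response (30, 0.030) were also higher and had 0 calls over all genes. Adjusted over the list alone 3 glycolysis genes rose and 0 genes of the other 3 lists passed, and all 4 list calls were lost with an estimated correlation (adjusted p = 0.51, 0.51, 0.53 and 0.53). Interferon-stimulated genes were lower as a list with 0 calls among 20 (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.017, adjusted p = 0.19 with an estimated correlation, 0.044 with the trend also removed). In the fixed list of 28 tested monocyte and macrophage genes, which leaves out MPEG1, only S100A8 passed (0 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.0050, adjusted p = 0.19 with an estimated correlation, 0.026 with the trend also removed). Neither the BCL2 family (0 of 18, also adjusted over the list alone, camera adjusted p = 0.62) nor the contact genes (0 of 50, also adjusted over the list alone, camera adjusted p = 0.56) had a call. Camera leaned up for both, against a median of -0.01 for the BCL2 family and a mean of -0.03 for the contact genes. In all, limma called 15 genes, 0 higher and 15 lower, 0 of them by 1 or more on the log2 scale, and 2011 genes had an unadjusted p under 0.05. By limma's voom on the recovered reads 15 genes passed, and the libraries did not overlap for 13.5% of genes, where chance gives 10%. The count rested on single libraries and on the model: it was 931 (519 higher and 412 lower) without DMSO replicate 2, 8 without ABT replicate 1 or 3, 4 without ABT replicate 2 and 3 without DMSO replicate 3. It was 142 (70 higher and 72 lower) with the replicate number as a block, 2352 (794 higher and 1558 lower) with the block over the 9 DMSO, ELI and ABT libraries alone, and 572 (329 higher and 243 lower) with the trend on GC content and length removed.

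Both drugs together lowered the whole replication list and many mitotic genes. Many genes of oxidative defence, glycosphingolipid metabolism and lysosomes rose, in lists whose calls were lost with an estimated correlation and the GC and length trend removed (adjusted p = 0.078, 0.20 and 0.20), for lysosomes also without that removal (0.10). Against DMSO, BHLHE40 rose by 3.48 (SE 0.08), COL6A1 by 2.73, LGALS2 by 2.55, heme oxygenase HMOX1 by 2.50, IL4I1 by 2.46, SIGLEC6 by 2.33, the chitinase-like gene CHI3L1 by 2.26 and ASAH1 by 2.18. HMOX1 went from 1.98 ± 0.373 to 15.8 ± 0.650 FPKM (SD, n = 3). S100A8 fell by 3.12 (SE 0.13) and S100A9 by 3.02, followed by IGLL1 (-2.36), the histone chaperone ASF1B (-2.33), thymidine kinase TK1 (-2.32), the kinetochore gene SPC24 (-2.27), the cell cycle factor MYBL2 (-2.19) and APOBEC3B (-2.08). All of these had limma adjusted p-values of 9.9e-08 or lower. S-phase genes fell in 47 of 47 cases (47 adjusted over the list alone), with RRM2 at -1.79, CDC6 at -1.76, MCM4 at -1.52 and MCM3 at -1.47 (median -1.50, camera adjusted p = 3.1e-31, adjusted p = 4.7e-05 with an estimated correlation). Of 44 mitotic genes 28 fell, 0 rose and 16 did not pass (29 fell adjusted over the list alone). Members included the kinase AURKB at -1.76, separase ESPL1 at -1.41, KIF2C at -1.28 and HJURP at -1.25 (list camera adjusted p = 6e-11, adjusted p = 0.030 with an estimated correlation). Among 23 oxidative defence genes driven by NRF2, 17 rose, 1 fell and 5 did not pass (18 and 1 adjusted over the list alone). Members included ferritin FTH1 at 1.88, the cystine transporter SLC7A11 at 1.52 and the quinone reductase NQO1 at 1.1. That list had a camera adjusted p of 4.3e-06 (adjusted p = 0.012 with an estimated correlation, 0.078 with the GC and length trend also removed). Glycosphingolipid and ceramide genes rose in 21 of 39 cases and fell in 5 (the same adjusted over the list alone), with the globotriaosylceramide synthase A4GALT at 1.31 and the sialidase NEU1 at 0.84 (camera adjusted p = 0.0024, adjusted p = 0.030 with an estimated correlation, 0.20 with the trend also removed). Lysosome genes rose in 31 of 44 cases and fell in 2 (the same adjusted over the list alone). Members included SQSTM1 at 1.39, CTSH at 1.24 and NPC2 at 0.77 (list camera adjusted p = 3.6e-07, adjusted p = 0.10 with an estimated correlation). NF-kB genes rose in 16 of 19 cases and fell in 1 (the same adjusted over the list alone), the exception being TNF at -0.90 (camera adjusted p = 7.9e-06, adjusted p = 0.080 with an estimated correlation). Cholesterol synthesis genes rose in 15 of 25 cases and fell in 2 (the same adjusted over the list alone). Members included INSIG1 at 1.67 and MSMO1 at 1.19 (list camera adjusted p = 0.0052, adjusted p = 0.18 with an estimated correlation). The integrated stress response list split, 9 up and 12 down of 30 (10 and 12 adjusted over the list alone, camera adjusted p = 0.49). Its serine synthesis genes PHGDH (-1.65) and PSAT1 (-1.05) fell while PPP1R15A, which restores translation after stress, rose by 1.00. Contact genes rose in 17 of 50 cases and fell in 8 (the same adjusted over the list alone, camera adjusted p = 0.59), with ITPR3 at -1.02 and the chaperone CANX at 0.52. In the BCL2 family 7 rose and 5 fell of 18 (7 and 6 adjusted over the list alone, camera adjusted p = 0.49), with BCL2L11 at 1.08 and BIK at -0.89. The number of genes called by limma was 5129, 2557 higher and 2572 lower, of which 390 changed by at least 1 on the log2 scale. Libraries did not overlap for 55.7% of genes, where chance gives 10%. The cholesterol call was lost without the libraries numbered 1 (camera adjusted p = 0.087).

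**Figure D3:**
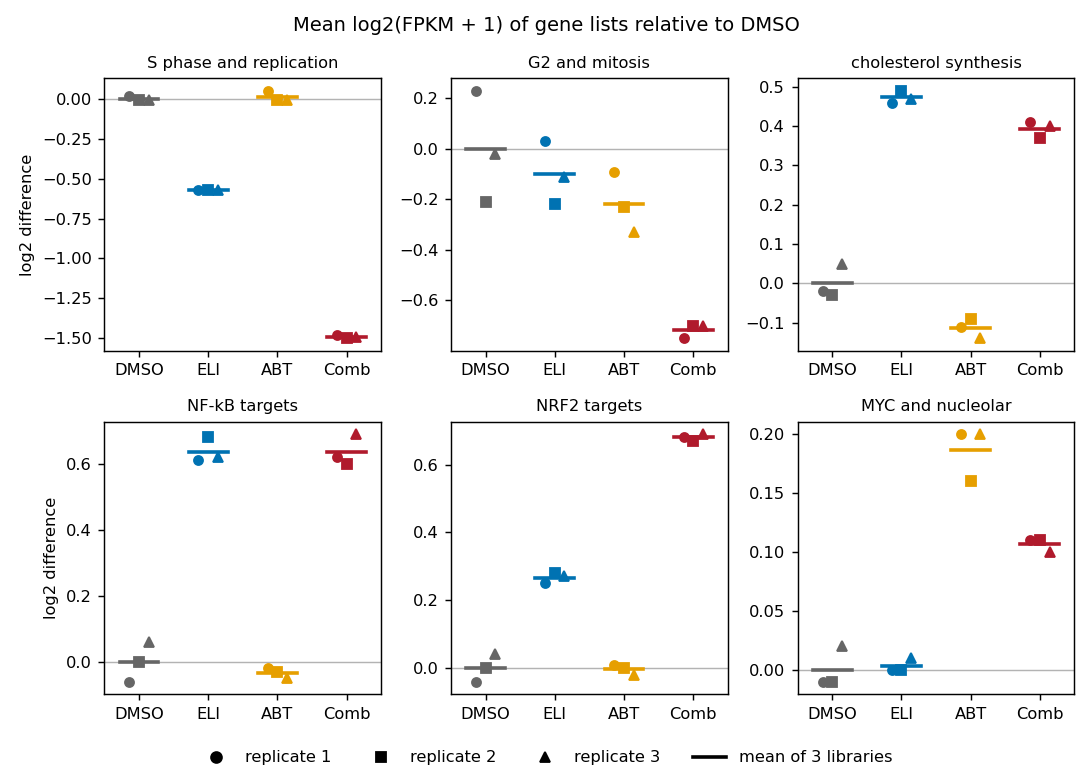
Mean log2(FPKM + 1) of the genes of 6 lists in each library relative to the mean of DMSO, with a symbol for each replicate number and a line at the mean of 3 libraries. The S-phase list is at -0.57 in the ELI libraries and between -1.50 and -1.48 in the Comb libraries.

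Adding eliglustat to venetoclax lowered the whole replication list and raised 17 of 23 oxidative defence genes. Against ABT, Comb cells carried more BHLHE40 (3.30, SE 0.08), LGALS2 (3.02), the chemokine CXCL8 (2.92, SE 0.23), SIGLEC6 (2.86), COL6A1 (2.78), HMOX1 (2.68), IL4I1 (2.58) and ASAH1 (2.48). CXCL8 went from 3 ± 1.33 to 28.2 ± 1.34 FPKM (SD, n = 3). They carried less S100A9 (-2.65, SE 0.11), S100A8 (-2.34), TK1 (-2.32), ASF1B (-2.32), MYBL2 (-2.29), SPC24 (-2.27), the origin recognition gene ORC1 (-2.22) and the helicase cofactor CDC45 (-2.22). Each had a limma adjusted p of 1e-06 or lower. S-phase genes fell in 47 of 47 cases (47 adjusted over the list alone, median -1.62, camera adjusted p = 4.2e-25, adjusted p = 0.00011 with an estimated correlation). Mitotic genes fell in 25 of 44 cases and rose in 1 (the same adjusted over the list alone). Members included the transcription factor FOXM1 at -1.67 and TPX2 at -1.02 (list camera adjusted p = 8.9e-06, adjusted p = 0.12 with an estimated correlation). Oxidative defence genes rose in 17 of 23 cases and fell in 1 (the same adjusted over the list alone). Members included FTH1 at 1.95 and SLC7A11 at 1.87 (list camera adjusted p = 0.00032, adjusted p = 0.044 with an estimated correlation, 0.10 with the GC and length trend also removed). Lysosome genes rose in 34 of 44 cases and fell in 3 (the same adjusted over the list alone, camera adjusted p = 4.2e-06, adjusted p = 0.12 with an estimated correlation). The stem and KMT2A program, whose genes maintain this kind of leukemia, rose in 13 of 15 cases and fell in 1 (the same adjusted over the list alone). Members included MEIS1 at 0.64 and HOXA10 at 0.33 (list camera adjusted p = 0.0038, adjusted p = 0.34 with an estimated correlation). Nuclear oxidative phosphorylation genes fell in 42 of 70 cases and rose in 7 (the same adjusted over the list alone). Members included UQCRC1 at -0.89 and NDUFV1 at -0.78 and NDUFC2 the other way at 0.89 (list camera adjusted p = 0.0020, adjusted p = 0.50 with an estimated correlation). Mitochondrial ribosome and import genes fell in 21 of 34 cases and rose in 4 (21 and 5 adjusted over the list alone), among them MRPL37 (-1.19) and the import channel TOMM40 (-0.82), with a camera adjusted p of 0.0049 (adjusted p = 0.14 with an estimated correlation). Mitochondrially encoded genes fell in 10 of 13 cases and rose in 0 (the same adjusted over the list alone). Members included MT-CYB at -0.51 and MT-CO3 at -0.50 (list camera adjusted p = 0.019, adjusted p = 0.51 with an estimated correlation). Among contact genes 22 rose and 16 fell of 50 (the same adjusted over the list alone, camera adjusted p = 0.83), with ITPR3 at -1.09, the actin regulator INF2 at -0.58, GSK3B at 0.68 and CANX at 0.62. The BCL2 family had 8 higher and 6 lower of 18 (8 and 7 adjusted over the list alone), with BNIP3L at 1.75, BCL2L11 at 1.11, BMF at 0.81 and BIK at -0.84. Its median was -0.02, its mean 0.19, and its camera direction up (camera adjusted p = 0.64). Comb and ABT differed in 6691 genes by limma, 3530 higher and 3161 lower, of which 685 changed by at least 1 on the log2 scale. Libraries did not overlap for 76.5% of genes, where chance gives 10%. With the GC and length trend removed 6755 genes passed, of which 4955 were shared with the 6691 in the same direction, and the share of higher calls went from 52.8 to 44.7%.

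Adding venetoclax to eliglustat lowered replication and mitosis genes and raised oxidative defence genes. Against ELI, HMOX1 rose by 2.43 (SE 0.11, limma adjusted p = 1.3e-07), from 2.14 ± 0.326 to 15.8 ± 0.650 FPKM (SD, n = 3). The TGF-beta pathway repressor SKIL (0.96), MS4A3 (0.92), PALD1 (0.89), NQO1 (0.89), ASAH1 (0.82), FTH1 (0.82) and CHI3L1 (0.80) rose as well. MPEG1 fell by 1.43 (SE 0.06, limma adjusted p = 1.1e-07), from 58.9 ± 1.08 to 21.2 ± 0.482 FPKM (SD, n = 3). The repressors E2F8 (-1.34) and E2F7 (-1.29), CDC45 (-1.29), ASF1B (-1.26), TK1 (-1.26), the activator E2F2 (-1.23) and CDC6 (-1.23) fell. All of these genes had limma adjusted p-values of 0.0049 or lower. S-phase genes fell in 47 of 47 cases (47 adjusted over the list alone), with RRM2 at -1.23, MCM4 at -0.98 and the sliding clamp PCNA at -0.94 (median -0.93, camera adjusted p = 8.3e-61, adjusted p = 3.4e-06 with an estimated correlation). Of 44 mitotic genes 29 fell, 0 rose and 15 did not pass (34 fell adjusted over the list alone). Members included HJURP at -0.90 and KIF2C at -0.83 (list camera adjusted p = 4.5e-27, adjusted p = 0.0016 with an estimated correlation). Oxidative defence genes rose in 7 of 23 cases and fell in 0 (12 and 0 adjusted over the list alone), with catalase CAT at 0.39 beside HMOX1, NQO1 and FTH1 (camera adjusted p = 6.1e-10, adjusted p = 0.0016 with an estimated correlation). Glycosphingolipid and ceramide genes rose in 5 of 39 cases and fell in 0 (the same adjusted over the list alone). Members included A4GALT at 1.1 and the saposin precursor PSAP at 0.55 (list camera adjusted p = 0.0043, adjusted p = 0.046 with an estimated correlation, 0.35 with the GC and length trend also removed). Integrated stress response genes fell in 7 of 30 cases and rose in 2 (8 and 3 adjusted over the list alone). Members included PHGDH at -0.95, PSAT1 at -0.75 and PCK2 at -0.62 (list camera adjusted p = 0.0036, adjusted p = 0.46 with an estimated correlation). Fatty acid synthesis genes fell in 5 of 17 cases and rose in 0 (8 and 1 adjusted over the list alone). Members included FADS1 at -0.52 and SREBF1 at -0.48 (list camera adjusted p = 0.0036, adjusted p = 0.31 with an estimated correlation). The p53 targets DDB2 (-0.72) and CDKN1A (-0.94) fell and TP53INP1 rose by 0.41, in a list with 1 higher, 3 lower and 22 not past the threshold (1 and 4 adjusted over the list alone, camera adjusted p = 0.52). Of 50 contact genes RAB32 rose, 3 fell and 46 did not pass (the same adjusted over the list alone, camera adjusted p = 0.47). The lowest adjusted p of those 3 was that of ITPR3 (-0.32, limma adjusted p = 0.014), which was lost without Comb replicate 3 (0.077), ELI replicate 1 (0.054) or ELI replicate 2 (0.069). By limma 951 genes passed, 302 higher and 649 lower, of which 39 changed by at least 1 on the log2 scale, 4 up and 35 down. Libraries did not overlap for 40.2% of genes, where chance gives 10%. The count was 624, 608 and 588 without Comb replicates 1, 2 and 3, 600 without ELI replicate 3, and 2396 with the GC and length trend removed. It was 2252 (999 higher) with only the 6 libraries fitted, 1607 with the block in these 6, and 1546 without the libraries numbered 1.

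The single drugs were also set against each other, which is the test of whether they differ. ELI exceeded ABT in IL4I1 (2.79, SE 0.11), BHLHE40 (2.57), SIGLEC6 (2.55), CD36 (2.51, SE 0.21), CXCL8 (2.43), LGALS2 (2.42), COL6A1 (2.14) and IL7R (2.11). It lay below ABT in IGLL1 (-1.77), S100A9 (-1.57), PLAC8 (-1.54), the adaptor gene APBB1IP (-1.52), S100A8 (-1.49), MS4A3 (-1.44), the arginine synthesis gene ASS1 (-1.35) and the amino acid transporter SLC38A5 (-1.22). All had limma adjusted p-values of 1.2e-05 or lower. S-phase genes were lower in 36 of 47 cases and higher in 0 (38 and 0 adjusted over the list alone, median -0.71, camera adjusted p = 6.8e-13, adjusted p = 0.0013 with an estimated correlation). MYC target and nucleolar genes were lower in 25 of 41 cases and higher in 7 (the same adjusted over the list alone). Members included the pyrimidine synthesis gene CAD at -0.90 and fibrillarin FBL at -0.79 (list camera adjusted p = 0.0046, adjusted p = 0.12 with an estimated correlation). Immediate early genes were higher in 16 of 28 cases and lower in 5 (the same adjusted over the list alone). Members included KLF6 at 1.97, KLF2 at 1.33, BTG2 at 1.3 and FOSB at 1.17 (list camera adjusted p = 0.0020, adjusted p = 0.088 with an estimated correlation). Targets of FLT3 and STAT5 were higher in 8 of 16 cases and lower in 2 (the same adjusted over the list alone), with the kinase PIM1 at 1.53, the feedback inhibitor SOCS3 at 1.1 and CCND2 at 0.72. That list had a camera adjusted p of 0.041 (adjusted p = 0.37 with an estimated correlation), and 0.079 with the replicate number as a block. Glycolysis genes were lower in 10 of 21 cases and higher in 5 (the same adjusted over the list alone), with GPI at -0.72 and LDHA at -0.45 (camera adjusted p = 0.062, and 0.047 with the block). Contact genes had 19 higher and 18 lower of 50 (the same adjusted over the list alone, camera adjusted p = 0.78), including RAB38 at 0.95 and LETM1 at -0.63. Their median was -0.05 and their mean 0.08. Between the single drugs 6279 genes differed by limma, 3310 higher and 2969 lower, of which 302 differed by at least 1 on the log2 scale. Libraries did not overlap for 71.2% of genes, where chance gives 10%. With the GC and length trend removed 5900 genes passed, 4138 of them shared in the same direction, and the share of higher calls went from 52.7 to 44.3%.

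Whether the combination departed from the sum of the single drug changes was tested as an interaction on the log2 scale. HMOX1 lay above that sum by 2.60 (SE 0.15, limma adjusted p = 5.3e-06), and H2AC6 (1.27), SKIL (1.24), ASAH1 (1.12), LGALS2 (1.08) and HLA-DRA (0.94) were among the other genes above it. CDC45 (-1.46, SE 0.12), E2F2 (-1.39), E2F7 (-1.28), TK1 (-1.26), the cell cycle gene TCF19 (-1.26), MYBL2 (-1.25), ASF1B (-1.25) and RRM2 (-1.21) lay below it. These genes had limma adjusted p-values of 0.015 or lower. TK1 was at 101 ± 12.8 FPKM in DMSO, 47.7 ± 4.30 in ELI, 100 ± 7.91 in ABT and 19.3 ± 1.33 in Comb (SD, n = 3). S-phase genes were below the sum in 41 of 47 cases and above it in 0 (43 and 0 adjusted over the list alone). Members included MCM4 at -1.19 and the flap endonuclease FEN1 at -1.19 (list median -0.93, camera adjusted p = 9.5e-50, adjusted p = 7.5e-06 with an estimated correlation). Mitotic genes were below it in 20 of 44 cases and above it in 0 (22 and 0 adjusted over the list alone). Members included KIF2C at -0.91 and UBE2C at -0.85 (list camera adjusted p = 4.9e-13, adjusted p = 0.019 with an estimated correlation). Oxidative defence genes were above it in 6 of 23 cases and below it in 0 (the same adjusted over the list alone), with NQO1 at 0.64 (camera adjusted p = 8.8e-06, adjusted p = 0.014 with an estimated correlation, 0.10 with the GC and length trend also removed). Integrated stress response genes were below it in 5 of 30 cases and above it in 2 (10 and 2 adjusted over the list alone). Members included PHGDH at -1.11 and PSAT1 at -0.95 (list camera adjusted p = 0.00032, adjusted p = 0.30 with an estimated correlation). No contact gene passed among 50 (0 also adjusted over the list alone, camera adjusted p = 0.95), and none of the 18 BCL2 family genes did (0 also adjusted over the list alone, camera adjusted p = 0.85). The BCL2 family had a median of -0.06, a mean of 0.02 and a camera direction down. In all, limma called 532 genes, 167 above and 365 below the sum, with a Spearman's rho of -0.50 between the interaction and GC content across genes. Without the libraries numbered 1 the balance turned over, with 1801 genes called by limma, 1072 above and 729 below the sum. The count was 983 with the replicate block and 1736 with the GC and length trend removed. It was 1123 without DMSO replicate 2, 326 without ABT replicate 2, 331 and 332 without Comb replicates 2 and 3, and 351 and 322 without ELI replicates 2 and 3.

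Genes whose level under both drugs lay beyond vehicle and beyond each single drug numbered 811, 243 higher and 568 lower. The higher ones with the largest differences were HMOX1, BHLHE40, LGALS2, COL6A1, ASAH1 and SKIL (1.87 against DMSO), and the lower ones were S100A9, TK1, ASF1B, CDC45 (-2.05 against DMSO), MYBL2 and E2F2 (-2.01 against DMSO). All 47 S-phase genes were among the 568 lower ones, against 2.7 from lists drawn independently, as were 25 of 44 mitotic genes, against 2.5. Of the 243 higher genes, 7 of 23 oxidative defence genes (0.6 from independent lists), 7 of 44 lysosome genes (1.1) and 4 of 39 glycosphingolipid genes (1.0) were members. A change of at least 0.5 on the log2 scale in each of the 3 comparisons was met by 297 genes, 40 higher and 257 lower. The count of 811 was 529 without Comb replicate 2, 518 without Comb replicate 3 and 531 without ELI replicate 3. It was 1323 without the libraries numbered 1 and 1896 with the GC and length trend removed.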

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

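The tests of GC content, of the libraries numbered 1 and of the pseudocount below were chosen after the results they bear on had been seen, except the GC test of the MYC list, the thinning of reads and the counts of other splits.

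The combined treatment departed from the sum of the single drug changes in 532 genes by limma's test of the interaction. The named genes above the sum were HMOX1 (2.60), CXCL8 (1.34), H2AC6 (1.27), SKIL (1.24), ASAH1 (1.12), FYB1 (1.1), LGALS2 (1.08) and HLA-DRA (0.94). Those below it were CDC45 (-1.46), E2F2 (-1.39), E2F7 (-1.28), TK1 (-1.26), TCF19 (-1.26), MYBL2 (-1.25), ASF1B (-1.25) and RRM2 (-1.21). CXCL8 (limma adjusted p = 0.035) lost its call without ABT replicate 2 (0.099) or 3 (0.089), Comb replicate 1 (0.072), 2 (0.094) or 3 (0.083), DMSO replicate 3 (0.058), or ELI replicate 2 (0.097) or 3 (0.090). FYB1 (limma adjusted p = 0.029) lost it without ABT replicate 2 (0.084) or 3 (0.080), Comb replicate 1 (0.060), 2 (0.086) or 3 (0.072), or ELI replicate 2 (0.084) or 3 (0.081). Among lists, the S-phase median was -0.93, the mitotic median -0.45 and the oxidative defence median 0.30. In 100 regroupings of the 12 libraries, the real one included, which did not keep same-numbered libraries apart, 3 gave as many genes for the interaction, a share under 0.05, and the highest other count was 5246. For the combination-enhanced set 2 of 100 did, with 811 genes in the real groups and 1399 in the highest other regrouping. Regroupings that call several times the real number of genes point to a structure of the samples, and since same-numbered libraries of 3 groups deviate together these shares do not settle chance under that pairing.

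For the fall of S-phase genes beyond the sum of the single drugs, the list mean was -0.93 (SE 0.024). It was -0.98 (SE 0.012) with the trend on GC content and gene length removed, -0.92 (SE 0.008) without the libraries numbered 1, and -1 (SE 0.027) with a pseudocount of 0.1. The trend as an explanation needed a mean near 0 once removed. The values under these settings show that the fall does not rest on them, but they could hardly have come out near 0. Mean levels of this list in replicates 1, 2 and 3 were 5.14, 5.11 and 5.11 in DMSO and 4.55, 4.56 and 4.55 in ELI. Spearman's rho of the deviation with GC content was -0.79, 0.81 and 0.40 in these DMSO libraries and -0.70, 0.69 and 0.19 in ELI. The list level thus did not follow the GC trend between libraries of these groups. Removing the trend or leaving out number 1 therefore had little to change. A smaller pseudocount widens differences between low values. The list means per library against DMSO were -0.57 in every ELI library, -0.01 to 0.05 in ABT and -1.50 to -1.48 in Comb. A candidate explanation is that the drugs together hold cells back from S phase more than either alone, but a change in the make-up of surviving cells stays open and was not tested. The list of replication histone genes did not fall, with means of 1.52 to 1.68 in DMSO and 1.70 to 1.81 in Comb. Its departure from the sum leaned up and did not pass (camera adjusted p = 0.12), the other way from the S-phase list. The histone levels are low against 5.11 to 5.14 for the S-phase list in DMSO, so their direction says little about S phase.

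Nucleolar and MYC target genes were higher in ABT than in DMSO with a list mean of 0.19 (SE 0.012), although no member passed over all genes. The mean was 0.20 (SE 0.014) with the GC and length trend removed, a trend that followed this comparison with a rho of 0.66. It was 0.17 (SE 0.016) without the libraries numbered 1. The list was at 4.4, 4.4 and 4.43 in DMSO replicates 1, 2 and 3 and at 4.61, 4.57 and 4.61 in ABT. DMSO replicates 1 and 2 had a rho with GC content of -0.79 and 0.81. The list level thus did not follow the trend between DMSO libraries, and both removals had little to change and could hardly have given a mean near 0. An effect of venetoclax on ribosome production may underlie it, as a hypothesis that comes from these data and was not tested.

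Replicate 1 of DMSO, ABT and ELI stood apart from replicates 2 and 3 of its group. A trend on GC content and length took 65.9% of the within-group variance of these 3 libraries. This value gives the size of a trend already seen in the same libraries and is no test of its cause. The trend as removed does not account for all of the pattern: the lowest of the 3 correlations between their deviations was 0.74 before and 0.43 after removal. None would be left if the trend were the whole cause and its removal complete. Since only 1 form of removal was tried, a remainder of the trend cannot be told apart from another cause. With all libraries thinned to equal depth the lowest correlation was 0.73. Totals before thinning were already close, at 17259905 to 21082313 reads, and FPKM values are scaled to the reads of the library. Thinning could thus hardly have lowered the correlation, and it does not decide whether depth plays a part. A shared culture or preparation of the libraries numbered 1 stays open, and the labels name no batch. The Comb libraries did not deviate together with the same-numbered libraries of the other groups (correlations of -0.40 to 0.16). Whether they were cultured or prepared apart is not given. If they were, that could not be told apart from the drugs in any comparison with Comb, the interaction or the combination-enhanced set.

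Splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. A split that mixes 2 differing groups also puts their difference into the spread within its parts. Where groups differ widely, a count of 0 in the other splits was thus nearly fixed in advance and is no support. The real split alone gave as many genes as it did for ELI against DMSO (1 of 10, 3600 genes, highest other 0), Comb against DMSO (1 of 10, 5129, highest other 0), Comb against ABT (1 of 10, 6691, highest other 0), Comb against ELI (1 of 10, 951, highest other 0) and ELI against ABT (1 of 10, 6279, highest other 0). For ABT against DMSO 2 of 10 did, and the other split gave 3713 genes against 15. It set ABT replicate 1, DMSO replicate 1 and DMSO replicate 3 against ABT replicates 2 and 3 and DMSO replicate 2, which points to a structure of the samples. Among the 4 splits that part all same-numbered pairs, the highest other count was 0, and the count with the replicate block was 142.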

How the results depend on the processing

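The fits without all libraries numbered 1, with the GC and length trend removed, by voom, rescaled outside mitochondrial genes, and with the block in 6 or 9 libraries were chosen after the results had been seen. No named gene or list changed direction in a setting where it passed. Among all genes, those that passed both before and after removal of the GC and length trend kept their direction in 4955 of 5141 cases for Comb against ABT and 4138 of 4291 for ELI against ABT. Counts for Comb against DMSO, Comb against ABT and ELI against ABT stayed within 1.5 times of the reported value under every alternative. The pseudocounts, the filters, voom and the mitochondrial rescaling moved no count by over 1.5 times. Median-of-ratios scaling did so only for ABT against DMSO (8 genes in place of 15). Fitting only the 6 libraries compared gave 1994 genes for ELI against DMSO, 0 for ABT against DMSO and 2252 for Comb against ELI. With the replicate block the count was 142 for ABT against DMSO and 983 for the interaction, and no other count moved by over 1.5 times in the 12-library fit. The block in 6 libraries gave 2028 for ABT against DMSO and 1607 for Comb against ELI, and in the 9 libraries of DMSO, ELI and ABT 2352 for ABT against DMSO. Among named genes and lists the 12-library block changed the calls of BCL2 (ELI against DMSO), FLT3 and STAT5 targets and glycolysis (both ELI against ABT). Without the libraries numbered 1 limma called 5581 genes for ELI against DMSO, 147 for ABT against DMSO, 1546 for Comb against ELI, 1801 for the interaction (1072 above and 729 below the sum) and 1323 for the combination-enhanced set. With the GC and length trend removed it called 572 for ABT against DMSO, 2396 for Comb against ELI, 1736 for the interaction and 1896 for the combination-enhanced set, and with the block as well 1134, 2788, 2182 and 2164. Fits of 6 libraries have fewer residual degrees of freedom, which by itself would not raise the Comb against ELI count from 951 to 2252. Such fits also take the spread from the compared groups alone, and the spread was unequal between groups. Chi-square per degree of freedom between libraries was 2.71 to 4.42 in Comb, 5.55 to 19.48 in ELI and 13.25 to 83.68 in DMSO. The cause of the changes under these settings was not tested.

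Leaving out 1 library at a time gave 2291 to 5871 genes for ELI against DMSO (5871 without DMSO replicate 1, 2291 without ELI replicate 1) and 3 to 931 for ABT against DMSO (931 without DMSO replicate 2, 3 without DMSO replicate 3, 4 without ABT replicate 2, 8 without ABT replicate 1 or 3). It gave 4086 to 6589 for Comb against DMSO, 5795 to 6756 for Comb against ABT and 4772 to 6487 for ELI against ABT. For Comb against ELI it gave 588 to 680 (624, 608 and 588 without Comb replicates 1, 2 and 3, 600 without ELI replicate 3). For the interaction it gave 322 to 1123 (1123 without DMSO replicate 2, 326 without ABT replicate 2, 331 and 332 without Comb replicates 2 and 3, 351 and 322 without ELI replicates 2 and 3). For the combination-enhanced set it gave 518 to 1213 (529 and 518 without Comb replicates 2 and 3, 531 without ELI replicate 3). Of the genes named, UGCG, BCL2 and RAB32 aside, 0 of 132 changed their call under any alternative in Comb against ABT, 1 of 131 in ELI against ABT, 2 of 131 in Comb against DMSO, 5 of 134 in ELI against DMSO, 18 of 82 in Comb against ELI, 18 of 52 in the interaction and 11 of 11 in ABT against DMSO. BCL2 changed its call in Comb against DMSO and ELI against DMSO, RAB32 in Comb against ELI and the interaction, and UGCG in ABT against DMSO and Comb against ELI. The tests on raw counts with DESeq2 and with edgeR glmTreat were kept for deposited counts and not run. On the recovered reads limma's voom was run. Depth limited low genes only: 1 read was worth about 0.01 FPKM.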

Other observations

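The test of whether changes follow GC content in the last paragraph was written before its result was seen, and the choice of gene groups described here was made after.

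Further fixed lists, LXR targets aside, held genes that rose and genes that fell in Comb against DMSO. Apart from hypoxia genes none of those described here passed as a list in that comparison. Of 14 tested replication histone genes, 6 rose, 4 fell and 4 did not pass in Comb against DMSO (the same adjusted over the list alone, camera adjusted p = 0.31), with H2AC6 at 1.68 and the linker histone H1-2 at -1.03. Interferon-stimulated genes split as well, 7 up and 7 down of 20 (7 and 8 adjusted over the list alone, camera adjusted p = 0.85), with IFITM1 at 1.69 and the deubiquitinase USP18 at -1.01. Metallothionein and heat shock genes had 5 higher and 4 lower of 20 (the same adjusted over the list alone, camera adjusted p = 0.99), among them MT2A at -0.78 and the zinc exporter SLC30A1 at 0.94. Among 33 Rab GTPases, the family of RAB32, 17 rose and 6 fell (the same adjusted over the list alone, camera adjusted p = 0.070), with RAB31 at 0.87, RAB10 at 0.67, RAB20 at 0.63 and RAB37 at -0.68. Autophagy genes rose in 15 of 34 cases and fell in 4 (the same adjusted over the list alone, camera adjusted p = 0.067), with NBR1 at 0.84 and GABARAPL1 at 0.71. In the list of apoptosis execution 4 rose and 9 fell of 27 (the same adjusted over the list alone, camera adjusted p = 0.28). CFLAR, which blocks caspase-8, rose (limma adjusted p = 5.3e-08), while PARP1 fell by 0.92 and CASP6 by 0.75. Calcium signalling genes had 10 higher and 7 lower of 34 (the same adjusted over the list alone, camera adjusted p = 0.72). LXR targets, which export cholesterol, had 0 higher and 2 lower of 7 in Comb against DMSO (0 and 4 adjusted over the list alone, camera adjusted p = 0.27), and ABCA1 rose by 0.86 in ELI against DMSO but fell by 0.74 in Comb against ELI (limma adjusted p = 9.2e-05). Hypoxia genes rose in 8 of 13 cases and fell in 2 in Comb against DMSO (the same adjusted over the list alone, camera adjusted p = 0.011, adjusted p = 0.080 with an estimated correlation), with VEGFA at 0.58. Ribosomal protein genes had 19 higher and 6 lower of 56 (18 and 5 adjusted over the list alone, camera adjusted p = 0.16), with RPS23 at 0.85. Mitochondrial stress genes had 4 higher and 9 lower of 23 (5 and 9 adjusted over the list alone, camera adjusted p = 0.67), with BNIP3L at 1.22 and the protease LONP1 at -0.62. Their median was -0.11 and their mean 0.03, with a camera direction down, and the metallothionein list had a median of -0.01 and a mean of 0.02, also with a camera direction down.

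Markers of other blood and tissue cell types were mostly near 0. Under 1 FPKM in every library were 8 of 10 matched B cell and plasma cell markers, 14 of 17 epithelial and stromal markers, 14 of 16 erythroid and megakaryocyte markers and 10 of 13 T and NK cell markers. Those above it included CD4, which monocytic cells express (118 FPKM in DMSO and 127 in Comb), NKG7 (53.4 and 40.6), IL7R (7.20 in DMSO, 27.8 in ELI, 5.73 in ABT and 17.8 in Comb), PECAM1 (13.6 in DMSO and 18.6 in ELI) and KRT18 (4.41 and 1.90).

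Comparisons that share no library were set side by side. The change made by adding eliglustat to venetoclax (Comb minus ABT) and that made by eliglustat alone (ELI minus DMSO) had a correlation across genes of 0.90, and 1497 genes were called higher in both where independent lists give 577.4, 1799 lower in both where they give 625.6, and 7 in opposite directions. With the GC and length trend removed the correlation was 0.88, so that trend is argued against as its main source, and a response to eliglustat that is largely kept in the presence of venetoclax is consistent with these values. For venetoclax the pattern differed: Comb minus ELI and ABT minus DMSO had a correlation of 0.03, or 0.08 with the trend removed, and 7 genes were lower in both where independent lists give 1.0, while 3 were opposite. An expected number of opposite calls was not computed. Removal of the trend thus moved this correlation little. With few genes called for venetoclax alone, a value near 0 over all genes cannot tell a small shared response from none. With the trend removed 572 genes passed for ABT against DMSO and 2396 for Comb against ELI, and their overlap was not computed. A venetoclax response that depends on eliglustat may be a hypothesis for these data. The 7 and 3 shared calls rest on the 15 genes called for venetoclax without the replicate block, and with the block that number was 142, or 2352 in the 9 libraries of DMSO, ELI and ABT.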
